A study of Mus musculus with 12 samples.

How the data were processed

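RNA-seq values of 12 libraries were used: whole testis, caput, corpus and cauda epididymidis of 3 wildtype C57BL/6J mice aged 10 to 12 weeks. Per the labels' protocols, tissues were snap frozen and lysed in Trizol, RNA was cleaned on RNeasy columns with DNase digestion, and 1 µg of total RNA went into a stranded total RNA kit (SMARTer Stranded Total RNA HI Mammalian). Per the submitters' processing notes, the tools named were FastQC, Trimmomatic 0.33, STAR 2.4.0a and featureCounts 1.4.5-p1 of Subread, with the genome build mm10 (GRCm38). The deposited table gives 1 score per gene and library, read counts that the authors normalised and rounded to whole numbers. The tool of that normalisation and the strand setting of the counting are not given in the sources used here. Counts from overlapping or antisense genes are therefore uncertain, as are those of near-identical copies such as the beta-defensins, the H2-Q genes and the Hsd3b genes. Gene identifiers, symbols and coordinates were taken from the deposited table; 99.8% of the identifiers were found in GENCODE release M21, and 80.0% of those had the same coordinates there.

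The table held 33402 genes, and the smallest maximum of any gene over the libraries was 4, so genes with lower values had been left out before deposit. Column totals were 19.6 to 28.8 M. In 11 libraries the low values skipped or doubled whole numbers in a regular rhythm, and in cauda of mouse 1 no rhythm could be told from a factor of 1. From this the factor between reads and values was estimated as 0.826 to 1.169, and as 0.996 in cauda of mouse 1; on simulated data with 12 known factors the largest error was 7.1e-05. Dividing by it gave the estimated reads per library. Where the factor was below 1, neighbouring read counts merge into 1 value and cannot be recovered, so the test planned for recovered reads was not run. Median ratios of the libraries to the gene-wise geometric mean were 0.984 to 0.994 over genes above 0 in all libraries. No library was a copy of another.

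What was computed from the values was as follows. Values were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend) on log2(value + 1), with the authors' normalisation kept. Genes with a value of at least 10 in at least 3 libraries were tested, 26732 in all, and the 12 libraries entered 1 fit with the tissue as the only term. The 6 pairwise comparisons were read from it, with Benjamini-Hochberg adjustment and a threshold of 0.05. All log2 fold changes are on the log2(value + 1) scale, which understates those of low genes, and SE is the moderated standard error. The SE rests on the spread within every tissue, so libraries of a tissue outside a comparison can widen it. Means and SDs are of the deposited values over the 3 libraries of a tissue. A gene was called enriched in a tissue when it was called and at least 2-fold higher there against each of the other tissues. With 3 libraries per tissue, values of a gene fail to overlap by chance in 10% of comparisons.

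A total of 43 gene lists were fixed before the data were examined, as were the tests, the filter and the rule for named genes. They cover germ cells, testicular somatic cells, epididymal secretory families and cell types, muscle, connective tissue, immune cells and pathways, mitochondrially encoded transcripts and proliferation. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01 and adjusted over the 258 tests of 43 lists in 6 comparisons, and again with an estimated correlation. No list call held with the estimated correlation. Members were counted after adjustment over all genes and adjusted over the list alone. Named genes were taken from the 8 with the largest log2 fold change in each direction among called genes with a symbol, a mean of at least 100 in the higher tissue and no overlap between the 3 libraries of each tissue, and from the 2 highest and 2 lowest called members of each list; some were left out. Per-library values given to show a library apart from its group, and the Hox genes, were chosen after their values were seen.

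The titles give the same first number in each tissue, which was read as the mouse, so libraries were taken to pair by animal. Deviations from the tissue means of libraries from the same mouse correlated at -0.043 to 0.022 over 18 pairs, with a median of -0.0065 against 0.001 for other pairs, and none was above 0.1. The fit with the mouse as a block was run as an alternative. Other alternatives were TMM and upper-quartile scaling, no filter and a filter of 50, pseudocounts of 0.1 and 10, robust variance moderation, fits of only the 2 regions compared or only the 3 epididymal regions, removal of genes at least 10 times higher in testis, and each library and each mouse left out. Scaling to the total without mitochondrial transcripts was added after the data were seen.

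The tests were checked on simulated data for cauda against caput, with 10 sets of values and 200 genes changed. Values were drawn around the real tissue means, with caput and cauda first set to their average. The spread of a gene was averaged over the tissues and used for all of them. Real replicates differed in spread, with a chi-square per gene against counting noise of 2.64 to 3.15 in testis and 21.85 to 52.53 in corpus. The false shares therefore cannot show the effect of unequal spread between tissues. On average 26052 genes passed the filter in the 12-library fit, 21210 with 9 libraries and 20405 with 6. The 12-library fit recovered 44.4% of 1.5-fold, 69.2% of 2-fold, 94.2% of 4-fold and 98.6% of 8-fold changes. On average 11.6% of its calls were false (8.9 to 15.1% over the sets), above the threshold of 5%, and 75.8% of the false calls were genes at least 5-fold higher in testis. With the 9 epididymal libraries the false share was 4.7%, and with the 6 libraries compared 6.1%. With 10693 genes changed, the 12-library, 9-library and 6-library fits gave 3.3%, 2.6% and 2.6% over 26122, 21408 and 20661 genes. In the list test on simulated data, 1 planted list was called at an adjusted p of 6.51e-34, and at 3.39e-05 with an estimated correlation, and 0 of 40 random lists were called.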

Results

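RNA from 4 male reproductive tissues of 3 wildtype C57BL/6J mice aged 10 to 12 weeks was sequenced. The tissues were whole testis, where sperm are made, and the caput, corpus and cauda epididymidis. These are the head, body and tail of the duct in which sperm mature and are stored. By the numbers in the titles, each mouse gave 1 library per tissue, which makes 12 libraries and n = 3 in every group. The series title concerns damage of these tissues in bacterial infection, and the labels of these libraries name no treatment. The deposited values, read counts normalised by the authors and rounded to whole numbers, listed 33402 genes. They summed to 23.9, 23.8 and 23.9 M in testis of mice 1, 2 and 3, and to 19.9, 20.2 and 19.6 M in caput. Corpus totals were 24.8, 28.8 and 27.1 M, and cauda totals 23.1, 21.4 and 23.3 M. Reads before normalisation, estimated from the spacing of the rounded values, were 24.1, 24.5 and 28.9 M in testis. In caput they were 20.4, 19.7 and 19.3 M, in corpus 25.6, 25.7 and 27.0 M, and in cauda 23.2, 18.3 and 20.6 M. Transcripts encoded by the mitochondrial genome made up 9.7 ± 0.529% of the values in testis and 22.5 ± 1.01% in caput (mean ± SD, n = 3). Their share was 44.3 ± 4.21% in corpus and 36.6 ± 2.37% in cauda. Totals without them were 21.5 ± 0.115 M in testis, 15.4 ± 0.0577 M in caput, 14.9 ± 0.0577 M in corpus and 14.3 ± 0.2 M in cauda.

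**Figure D1:**
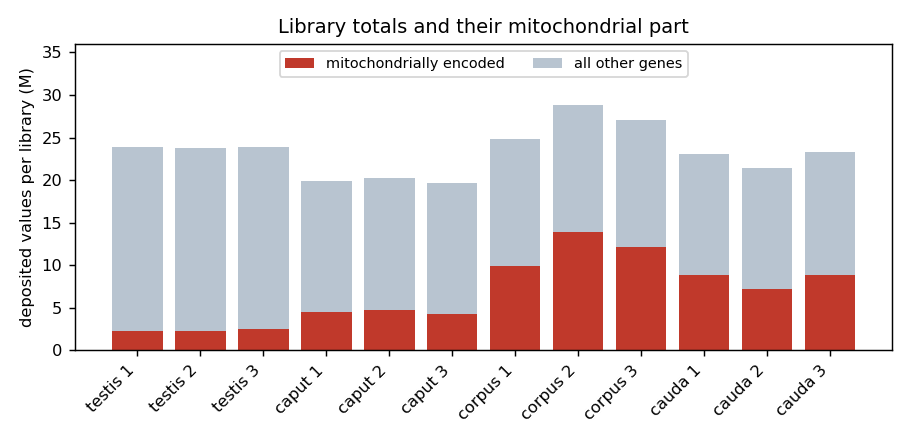
Deposited totals of the 12 libraries in M normalised read counts, each bar split into mitochondrially encoded transcripts and all others. The mitochondrial share ran from 9.3% in testis of mouse 2 to 48.3% in corpus of mouse 2.

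Libraries of the same tissue were close to each other across the 26732 genes with a value of at least 10 in at least 3 libraries. Pearson correlations of log2 values were 0.978 to 0.992 within a tissue, 0.893 to 0.955 between epididymal regions and 0.497 to 0.548 between testis and epididymis. They are across genes, which are not independent replicates. limma called 13044 genes between cauda and caput at an adjusted p below 0.05, 11713 between corpus and caput, and 9864 between cauda and corpus. Testis differed from caput in 22722 genes, from corpus in 22935 and from cauda in 22901. Cauda had 4173 genes at least 2-fold higher and 2766 at least 2-fold lower than caput. The same counts were 3381 and 2642 for corpus against caput, and 2457 and 2019 for cauda against corpus. In testis, 11040, 11166 and 11267 genes were at least 2-fold higher than in caput, corpus and cauda, and 7219, 7226 and 7225 lower. False shares were estimated in simulated data that gave each gene the same spread in all tissues. With 200 changed genes, 11.6% of calls between cauda and caput were false in the 12-library fit, against 4.7% with the 9 epididymal libraries. With 10693 changed genes, closer to the counts called here, the false shares of these 2 fits were 3.3% and 2.6%. With those 9 libraries the counts within the epididymis were 11728, 10640 and 8930. The balance of directions depended on the setting. In cauda 7043 genes were called higher and 6001 lower than in caput, against 5746 and 5982 with the 9 libraries. For corpus and caput the counts were 6274 and 5439, against 5288 and 5352. For cauda and corpus they were 5015 and 4849, against 4400 and 4530, and 4631 and 5453 with upper-quartile scaling. Scaled to the total without mitochondrial transcripts they were 8246 and 4974, 6751 and 5000, and 5741 and 4224.

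**Figure D2:**
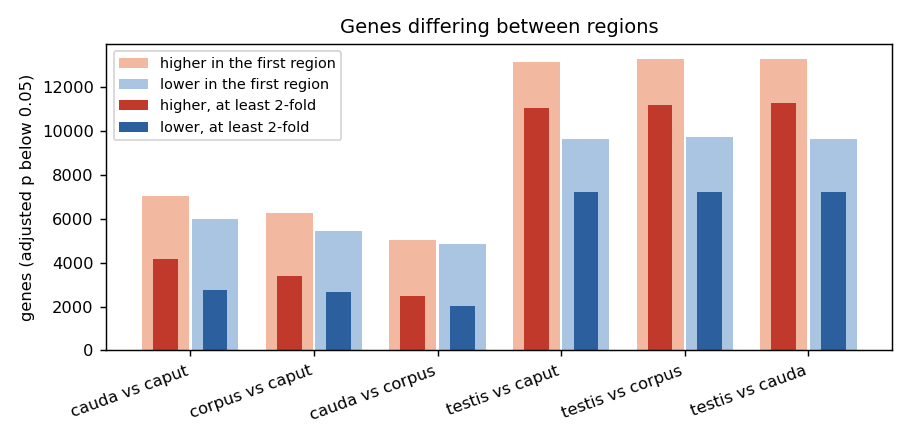
Number of genes called by limma at an adjusted p below 0.05 in each of the 6 pairwise comparisons, higher or lower in the tissue named first. Narrow dark bars count genes at least 2-fold apart, and comparisons with testis gave 22722 to 22935 genes in all.

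The comparison of cauda with caput asked how the storage end of the duct differs from its head, and genes of secreted proteins were among those named for their large fold changes. Ltf, which encodes the iron-binding protein lactoferrin, averaged 18947 ± 2675 in cauda against 9.33 ± 11.8 in caput (log2 fold change 11.48, SE 0.64, adjusted p = 2.21e-08). Its log2 fold change was 12.41 without caput of mouse 2, which held 23 against a mean of 2.5 in those of mice 1 and 3. Crisp1, a cysteine-rich protein that coats sperm, averaged 392879 ± 67601 in cauda against 5935 ± 3196 in caput (log2 fold change 6.17, SE 0.38, adjusted p = 5.59e-08). The lipocalin Lcn9, of a family that carries small lipophilic molecules, averaged 2.33 ± 2.52 in cauda against 58429 ± 4538 in caput (log2 fold change -14.44, SE 0.64, adjusted p = 3.11e-09). Without cauda of mouse 1 or of mouse 2 its log2 fold change was -13.75 and -15.04. Cst11, of the cystatin family of cysteine protease inhibitors, averaged 1 ± 1 in cauda against 22471 ± 2202 in caput (log2 fold change -13.59, SE 0.64, adjusted p = 4.89e-09). Lcn10 was listed at 0 in all cauda libraries and averaged 7634 ± 603 in caput. On GRCm38, Ltf (ENSMUSG00000032496) lies on chromosome 9 at 111019271 to 111042767, and Crisp1 (ENSMUSG00000025431) on chromosome 17 at 40293758 to 40319207. Lcn9 (ENSMUSG00000023210) and Cst11 (ENSMUSG00000036958) lie on chromosome 2, at 25823153 to 25825537 and 148768609 to 148771497. Cwh43, Hephl1 and Gabrp, a subunit of GABA type A receptors, were also far above caput (log2 fold changes 10.29, 9.81 and 8.65). Cwh43 had 11.22 without caput of mouse 2 and 9.52 without caput of mouse 3. Adam28, of the ADAM metalloprotease family, and the lipocalin Lcn8 were far below it (-12.33 and -12.19).

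Secreted protein families were counted by list. Of the lipocalins, 1 of 10 measured members was higher and 7 lower (adjusted p = 1.7e-05, and adjusted p = 0.0574 with an estimated correlation). Of the beta-defensins, secreted antimicrobial peptides whose near-identical copies can share reads, 12 of 36 measured members were higher and 21 lower (adjusted p = 0.0123, and adjusted p = 0.399 with an estimated correlation). Defb9 and Defb40 were higher (log2 fold changes 8.88 and 8.56), and Defb41 and Defb25 lower (-12.67 and -11.24). Without cauda of mouse 2, Defb41 had -13.27. Among cystatins and serine protease inhibitors, 15 of 32 measured members were higher and 13 lower (adjusted p = 0.897). The median log2 fold change of that list, 0.62, and its mean, -1.03, differed in sign. Serpine2, an inhibitor of thrombin and plasminogen activators, averaged 7295 ± 107 in cauda against 134 ± 52 in caput (log2 fold change 5.85, SE 0.41, adjusted p = 1.48e-07). Among sperm maturation proteins of the epididymis, 13 of 36 measured members were higher and 18 lower, 14 and 18 adjusted over the list alone (adjusted p = 0.0829). Leaving out corpus of mouse 1 or of mouse 2 from the fit gave that list adjusted p = 0.0467 and 0.0343. The beta-defensin call ended in the fit of epididymal libraries or with genes at least 10 times higher in testis removed (adjusted p up to 0.102).

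Single transport genes differed widely between cauda and caput, although the transport lists were not called. Cftr, the chloride and bicarbonate channel of epithelia, averaged 32.7 ± 2.08 in cauda against 4409 ± 251 in caput (log2 fold change -7.03, SE 0.24, adjusted p = 3.99e-10). Slc9a3, a sodium-proton exchanger of the apical membrane, averaged 1937 ± 116 in cauda against 56 ± 21.8 in caput (log2 fold change 5.17, SE 0.45, adjusted p = 9.9e-07). In the list of ion and water transport, 12 of 25 measured members were higher and 6 lower (adjusted p = 0.283). For clear and narrow cells, which acidify the lumen, 8 of 15 measured members were higher and 3 lower, 9 and 3 adjusted over the list alone (adjusted p = 0.179). Their proton pump subunit Atp6v1c2 was higher (log2 fold change 3.61, SE 0.12, adjusted p = 4.83e-10). Of the smooth muscle genes, 18 of 20 measured members were higher and 1 lower (adjusted p = 1.49e-08, and adjusted p = 0.255 with an estimated correlation). Des, the intermediate filament desmin, averaged 8195 ± 2156 in cauda against 558 ± 98.6 in caput (log2 fold change 3.85, SE 0.18, adjusted p = 5.39e-09). Actg2, the gamma smooth muscle actin, was the exception and averaged 6967 ± 1752 in cauda against 16275 ± 253 in caput (log2 fold change -1.26, SE 0.13, adjusted p = 6.99e-06). Among collagens and extracellular matrix, 24 of 29 measured members were higher and 1 lower (adjusted p = 1.08e-06, and adjusted p = 0.399 with an estimated correlation). Fn1, fibronectin, averaged 5979 ± 1173 in cauda against 495 ± 41.3 in caput (log2 fold change 3.58, SE 0.12, adjusted p = 3.49e-10). Of the endothelial genes, 1 of 19 measured members was higher and 9 lower (adjusted p = 0.0169, and adjusted p = 0.342 with an estimated correlation), a call that ended at some settings (up to 0.0933). For the androgen and steroid response list, 5 of 17 measured members were higher and 7 lower (adjusted p = 0.183). Its member Srd5a2, a steroid 5-alpha-reductase, averaged 225 ± 35.2 in cauda against 1484 ± 55.1 in caput (log2 fold change -2.73, SE 0.18, adjusted p = 1e-07). Skeletal muscle genes gave 6 higher and 0 lower of 10 (adjusted p = 0.0563, and adjusted p = 0.0409 with the mouse as a block). Without cauda of mouse 1 or of mouse 3 that list had adjusted p = 0.0167 and 0.0141, and without cauda of mouse 2 it had 0.146. Cauda of mouse 2 stood apart, with the muscle myosin Myh1 at 10585 against 63 and 76 in those of mice 1 and 3. Ckm, muscle creatine kinase, had a log2 fold change of 4.84, and of 3.76 without cauda of mouse 2. It was 5.51 without cauda of mouse 3 and 4.18 without caput of mouse 2.

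Transcripts known from the testis differed between cauda and caput as well. Of the genes of spermatids and sperm, 26 of 31 measured members were higher and 1 lower, 27 and 1 adjusted over the list alone (adjusted p = 9.47e-11, and adjusted p = 0.1 with an estimated correlation). Prm2, a protamine that replaces histones in sperm chromatin, averaged 2718 ± 394 in cauda against 182 ± 48.1 in caput (log2 fold change 3.92, SE 0.20, adjusted p = 1.03e-08). It lies on chromosome 16 at 10791380 to 10796134 (ENSMUSG00000038015). Of the genes of meiotic spermatocytes, 13 of 20 measured members were higher and 2 lower, 14 and 2 adjusted over the list alone (adjusted p = 0.00135, and adjusted p = 0.148 with an estimated correlation). That call ended when genes at least 10 times higher in testis than in every epididymal region were removed (adjusted p = 0.312). Among Sertoli cell genes, 4 of 20 measured members were higher and 12 lower, 4 and 13 adjusted over the list alone (adjusted p = 0.00133, and adjusted p = 0.0761 with an estimated correlation). Their lower members included the cystatin Cst12, listed at 0 in cauda and at 2541 ± 444 in caput. Over 17 Sertoli list members with a mean of at least 100 in testis, the median caput level was 24.2% of that in testis. For spermatids and sperm it was 0.323%. A fall of the Sertoli list from caput therefore need not come from Sertoli cells. The mitochondrially encoded transcripts, 22.5% of the values in caput and 36.6% in cauda, gave 9 higher and 0 lower of 10, 10 and 0 adjusted over the list alone (adjusted p = 0.00993, and adjusted p = 0.522 with an estimated correlation).

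Immune genes went both ways between cauda and caput. Lcn2, which binds bacterial siderophores, averaged 972 ± 144 in cauda against 31435 ± 2203 in caput (log2 fold change -5.02, SE 0.13, adjusted p = 5.64e-11). B2m, the light chain of MHC class I, averaged 38382 ± 5483 in cauda against 10023 ± 373 in caput (log2 fold change 1.93, SE 0.13, adjusted p = 9.16e-08). Fst, which encodes the activin-binding protein follistatin, averaged 562 ± 80.5 in cauda against 16 ± 2.65 in caput (log2 fold change 5.05, SE 0.19, adjusted p = 8.18e-10). The activin subunits Inhbb and Inhba had log2 fold changes of -4.99 and -2.93. Klrb1c, from the list of NK and innate lymphoid cells, averaged 3.33 ± 1.53 in cauda against 2622 ± 469 in caput (log2 fold change -9.28, SE 0.42, adjusted p = 3.61e-09). It was the only lower member of that list, which gave 3 higher and 1 lower of 8 (adjusted p = 0.542). The median log2 fold change of the list, 0.65, and its mean, -0.56, differed in sign. For interferon-stimulated genes, 11 of 41 measured members were higher and 2 lower, 10 and 2 adjusted over the list alone (adjusted p = 0.0782). Without caput or without corpus of mouse 2 that list had adjusted p = 0.0343 and 0.0464. Blood cell genes gave 0 higher and 2 lower of 7 (adjusted p = 0.57).

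Corpus was compared with caput to describe the body of the duct against its head. Gpx5, a glutathione peroxidase secreted onto sperm, averaged 527 ± 818 in corpus against 549130 ± 40965 in caput (log2 fold change -11.78, SE 1.00, adjusted p = 1.01e-06). It was 1471 in corpus of mouse 1 against 32 and 77 in those of mice 2 and 3. Without corpus of mouse 1 the log2 fold change of Gpx5 was -13.40, and without corpus of mouse 2 it was -10.66. Rnase10, of a secreted ribonuclease family, averaged 3.67 ± 1.53 in corpus against 33548 ± 4888 in caput (log2 fold change -12.86, SE 0.29, adjusted p = 2.16e-11). Lcn9, Cst11 and Adam28 were also lower (log2 fold changes -13.47, -13.45 and -12.46). On the higher side stood Cwh43 at 12176 ± 2530 in corpus against 13 ± 15.7 in caput (log2 fold change 10.42, SE 0.66, adjusted p = 7.52e-08). Without caput of mouse 2 or of mouse 3 its log2 fold change was 11.35 and 9.65. Cacna1b, a neuronal calcium channel subunit, averaged 1525 ± 253 in corpus against 1 ± 1 in caput (log2 fold change 9.70, SE 0.40, adjusted p = 1.91e-09). Npy, neuropeptide Y, averaged 13546 ± 3687 in corpus against 80 ± 10.4 in caput (log2 fold change 7.35, SE 0.46, adjusted p = 6.93e-08). Cyp17a1, an enzyme of androgen synthesis, averaged 2944 ± 458 in corpus against 98 ± 26.3 in caput (log2 fold change 4.92, SE 0.44, adjusted p = 1.72e-06). Gpx5 (ENSMUSG00000004344) lies on chromosome 13 at 21286429 to 21292731, and Cwh43 (ENSMUSG00000029154) on chromosome 5 at 73406075 to 73453435.

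Of the secreted families, only the lipocalins were called as a list between corpus and caput, and not with an estimated correlation. Of the beta-defensins, 15 of 36 measured members were higher and 13 lower (adjusted p = 0.881). Defb22, a part of the sperm glycocalyx on chromosome 2 at 152485663 to 152490138 (ENSMUSG00000027468), averaged 11663 ± 1420 in corpus against 36.3 ± 12.9 in caput (log2 fold change 8.33, SE 1.18, adjusted p = 8.66e-05). Spag11b averaged 31.3 ± 9.02 in corpus against 44057 ± 4787 in caput (log2 fold change -10.45, SE 0.27, adjusted p = 6.29e-11). The lipocalins gave 1 higher and 7 lower of 10 (adjusted p = 2.06e-05, and adjusted p = 0.0574 with an estimated correlation). Cystatins and serine protease inhibitors gave 15 higher and 10 lower of 32, 16 and 11 adjusted over the list alone (adjusted p = 0.612). Sperm maturation proteins gave 15 higher and 16 lower of 36, 16 and 16 adjusted over the list alone (adjusted p = 0.82), with a median log2 fold change of 0.02 and a mean of -1.48. The serine protease inhibitor genes Spint4 and Spint5 had log2 fold changes of 8.37 and 8.23 (adjusted p = 0.00309 and 0.00233). Caput of mouse 2 held 4675 of Spint4, and those of mice 1 and 3 held 3 and 8. Without that library the log2 fold changes of Spint4 and Spint5 were 11.57 and 11.16. Without caput of mouse 1 they were 6.47 and 6.01, and without caput of mouse 3 they were 7.06 and 7.51. Leaving out all libraries of mouse 1 or of mouse 3 ended the calls of Spint4 (adjusted p = 0.103 and 0.12) and Spint5 (0.0662 and 0.107).

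Genes of transport, muscle and immunity were counted by list for corpus and caput. Ion and water transport gave 10 higher and 8 lower of 25, 11 and 8 adjusted over the list alone (adjusted p = 0.727), and clear and narrow cells 7 higher and 3 lower of 15 (adjusted p = 0.353). Of their members, Cftr and the bicarbonate transporter Slc4a4 were lower (log2 fold changes -7.36 and -4.43). Atp6v1c2 and the carbonic anhydrase Car2 were higher (3.86 and 2.45). Actg2 averaged 288 ± 16.9 in corpus against 16275 ± 253 in caput (log2 fold change -5.82, SE 0.13, adjusted p = 2.5e-11). Smooth muscle genes gave 3 higher and 7 lower of 20 (adjusted p = 0.0421, and adjusted p = 0.636 with an estimated correlation). That call ended without caput of mouse 1 (0.106), corpus of mouse 2 (0.0664), corpus of mouse 3 (0.0587) or all of mouse 1 (0.107). It also ended in the fit of epididymal libraries (0.113) and with genes at least 10 times higher in testis removed (0.126). A filter of 50 (0.0604) and the fit of only the 2 regions (0.061) ended it as well. Endothelial genes gave 1 higher and 13 lower of 19 (adjusted p = 0.000826, and adjusted p = 0.179 with an estimated correlation). Chemokine and cytokine receptors gave 3 higher and 12 lower of 35 (adjusted p = 0.0206, and adjusted p = 0.275 with an estimated correlation), and lost the call at some settings (up to 0.0601). Il4ra, the interleukin 4 receptor, averaged 335 ± 89.1 in corpus against 1586 ± 135 in caput (log2 fold change -2.27, SE 0.18, adjusted p = 6.57e-07). Immediate early and heat shock genes gave 2 higher and 11 lower of 22, 3 and 11 adjusted over the list alone (adjusted p = 0.0416, and adjusted p = 0.349 with an estimated correlation). Without caput of mouse 1 or 2, corpus of mouse 3 or cauda of mouse 2 they had adjusted p = 0.051, 0.0535, 0.055 and 0.0577. They also lost the call in the fit of epididymal libraries (0.0985) and with genes at least 10 times higher in testis removed (0.0938). The same held for a filter of 50 (0.0845), the fit of only the 2 regions (0.0775) and all of mouse 2 left out (0.0735). Egr2, a transcription factor induced by growth factors, averaged 429 ± 190 in corpus against 4454 ± 344 in caput (log2 fold change -3.48, SE 0.25, adjusted p = 2.61e-07). Interferon-stimulated genes gave 3 higher and 8 lower of 41, 3 and 7 adjusted over the list alone (adjusted p = 0.065, and adjusted p = 0.0441 with the mouse as a block). Without testis or caput of mouse 1 or corpus of mouse 2 that list had adjusted p = 0.0411, 0.00932 and 0.013.

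Germ cell and mitochondrial transcripts differed too. Genes of spermatids and sperm gave 27 higher and 1 lower of 31 (adjusted p = 1.47e-08, and adjusted p = 0.123 with an estimated correlation). Meiotic spermatocytes gave 12 higher and 3 lower of 20 (adjusted p = 0.0129, and adjusted p = 0.243 with an estimated correlation), which ended with genes at least 10 times higher in testis removed (0.181). Sertoli cell genes gave 3 higher and 10 lower of 20, 3 and 11 adjusted over the list alone (adjusted p = 0.0014, and adjusted p = 0.0761 with an estimated correlation). Mitochondrially encoded transcripts gave 10 higher and 0 lower of 10 (adjusted p = 5.29e-05, and adjusted p = 0.362 with an estimated correlation). The messenger RNA mt-Nd2 averaged 114323 ± 29350 in corpus against 26965 ± 4998 in caput (log2 fold change 2.06, SE 0.19, adjusted p = 2.4e-06). Fat cell genes gave 3 higher and 1 lower of 14 (adjusted p = 0.211, and adjusted p = 0.0385 without corpus of mouse 3).

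The cauda and corpus comparison set the storage region beside the region just before it, and muscle and connective tissue genes were higher in cauda. Of the smooth muscle genes, 19 of 20 measured members were higher and 0 lower (adjusted p = 8.12e-17, and adjusted p = 0.123 with an estimated correlation). Actg2 averaged 6967 ± 1752 in cauda against 288 ± 16.9 in corpus (log2 fold change 4.56, SE 0.13, adjusted p = 1.39e-09), and Des 8195 ± 2156 in cauda against 382 ± 39.8 in corpus (log2 fold change 4.39). Of the collagens and extracellular matrix, 27 of 29 measured members were higher and 0 lower (adjusted p = 3.01e-11, and adjusted p = 0.249 with an estimated correlation). Fn1 averaged 5979 ± 1173 in cauda against 713 ± 4.93 in corpus (log2 fold change 3.05, SE 0.12, adjusted p = 6.81e-09). Chrm2, the muscarinic acetylcholine receptor M2, averaged 847 ± 180 in cauda against 4.67 ± 1.15 in corpus (log2 fold change 7.22, SE 0.34, adjusted p = 2.35e-08). Ano1, a calcium-activated chloride channel, averaged 8011 ± 565 in cauda against 956 ± 181 in corpus (log2 fold change 3.08, SE 0.12, adjusted p = 9.91e-09). Among secreted protease inhibitors, Spink14 averaged 1079 ± 234 in cauda against 4.33 ± 1.15 in corpus (log2 fold change 7.66, SE 0.42, adjusted p = 8.26e-08). Spint4 (ENSMUSG00000017310, chromosome 2, 164698501 to 164702453) averaged 3.67 ± 2.52 in cauda against 19041 ± 6277 in corpus (log2 fold change -12.11, SE 1.90, adjusted p = 0.000302). Its SE pools the spread of all tissues. Caput, outside this comparison, held 4675 of Spint4 in mouse 2 against a mean of 5.5 in mice 1 and 3. Of the beta-defensins, 5 of 36 measured members were higher and 19 lower, 6 and 19 adjusted over the list alone (adjusted p = 0.000529, and adjusted p = 0.248 with an estimated correlation). Of the sperm maturation proteins, 6 of 36 measured members were higher and 19 lower (adjusted p = 0.0116, and adjusted p = 0.497 with an estimated correlation). Genes of spermatids and sperm gave 19 higher and 0 lower of 31, 21 and 0 adjusted over the list alone (adjusted p = 1.7e-05, and adjusted p = 0.214 with an estimated correlation). Mitochondrially encoded transcripts gave 0 higher and 7 lower of 10, 0 and 8 adjusted over the list alone (adjusted p = 0.00373, and adjusted p = 0.497 with an estimated correlation). Corpus of mouse 2 held less of some secreted products than those of mice 1 and 3. Lcn5 was 2189 there against 40563 and 28028, and Muc15 437 against 15082 and 7614.

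Several immune lists were also higher in cauda than in corpus. Of the interferon-stimulated genes, 26 of 41 measured members were higher and 1 lower, 29 and 1 adjusted over the list alone (adjusted p = 9.59e-06, and adjusted p = 0.349 with an estimated correlation). Mx1, an antiviral GTPase, averaged 97.3 ± 14.4 in cauda against 31.3 ± 10.4 in corpus (log2 fold change 1.64, SE 0.24, adjusted p = 0.000158). Of the toll-like receptors and adaptors, 11 of 28 measured members were higher and 1 lower (adjusted p = 0.0118, and adjusted p = 0.274 with an estimated correlation). Tlr3, a sensor of double-stranded RNA, averaged 1040 ± 63.7 in cauda against 346 ± 53.9 in corpus (log2 fold change 1.59, SE 0.13, adjusted p = 1.94e-06). Of the genes of immune regulation and tolerance, 14 of 30 measured members were higher and 3 lower (adjusted p = 0.00559, and adjusted p = 0.27 with an estimated correlation). Fst averaged 562 ± 80.5 in cauda against 42 ± 4.58 in corpus (log2 fold change 3.71, SE 0.19, adjusted p = 4.47e-08). Of the 14 mast cell genes listed, only 5 were measured. They gave 3 higher and 0 lower, 4 and 0 adjusted over the list alone (adjusted p = 0.00235, and adjusted p = 0.323 with an estimated correlation). Among them the transcription factor Gata2 averaged 2472 ± 178 in cauda against 207 ± 26.8 in corpus (log2 fold change 3.57, SE 0.13, adjusted p = 5.42e-09). Hdc, the histidine decarboxylase, averaged 145 ± 18.1 in cauda against 10.3 ± 1.53 in corpus (log2 fold change 3.69, SE 0.26, adjusted p = 5.78e-07). Cytokines gave 10 higher and 1 lower of 23 (adjusted p = 0.0271, and adjusted p = 0.146 with an estimated correlation). Tnfsf13b, a B cell activating factor, averaged 84 ± 22.9 in cauda against 13.3 ± 5.51 in corpus (log2 fold change 2.62, SE 0.34, adjusted p = 7.06e-05). Over all settings the adjusted p of the toll-like receptors reached 0.0832 and that of cytokines 0.0528.

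Weaker calls between cauda and corpus depended on single libraries. Macrophage genes gave 12 higher and 3 lower of 26 (adjusted p = 0.021, and adjusted p = 0.567 with an estimated correlation). Itgam, an integrin of myeloid cells, averaged 280 ± 13.3 in cauda against 61 ± 27.8 in corpus (log2 fold change 2.27, SE 0.25, adjusted p = 1.64e-05). NOD-like receptors and inflammasome genes gave 8 higher and 1 lower of 20, 9 and 1 adjusted over the list alone (adjusted p = 0.0367, and adjusted p = 0.326 with an estimated correlation). Complement gave 13 higher and 2 lower of 29, 14 and 2 adjusted over the list alone (adjusted p = 0.0443, and adjusted p = 0.423 with an estimated correlation, and adjusted p = 0.0516 with the mouse as a block). Without corpus of mouse 1 or corpus of mouse 3, the calls ended for macrophages (0.0686 and 0.0707), NOD-like receptors (0.0626 and 0.0732) and complement (0.0874 and 0.0891). Without cauda of mouse 2 those of NOD-like receptors (0.0611) and complement (0.0905) ended. Antimicrobial proteins gave 5 higher and 1 lower of 16 (adjusted p = 0.0482, and adjusted p = 0.326 with an estimated correlation). That call ended without testis of mouse 1 (0.0512), corpus of mouse 1 (0.0585), cauda of mouse 2 (0.0767) or cauda of mouse 3 (0.0542). Proliferation genes gave 5 higher and 0 lower of 20, 4 and 0 adjusted over the list alone (adjusted p = 0.0298, and adjusted p = 0.581 with an estimated correlation). They lost the call without corpus of mouse 2 (0.0757), corpus of mouse 3 (0.102) or cauda of mouse 1 (0.136). Over all settings the adjusted p reached 0.0929 for macrophages, 0.485 for NOD-like receptors, 0.113 for complement, 0.107 for antimicrobial proteins and 0.226 for proliferation. Skeletal muscle genes gave 4 higher and 0 lower of 10 (adjusted p = 0.0182, and adjusted p = 0.579 with an estimated correlation), and adjusted p = 0.0742 without cauda of mouse 2. Myh1 was 10585 in that library against 63 and 76 in the other cauda libraries.

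Lists of other immune and tissue cells were not called between cauda and corpus. Chemokines gave 4 higher and 2 lower of 23 (adjusted p = 0.342), and dendritic cells 3 higher and 0 lower of 18 (adjusted p = 0.253). Monocytes and neutrophils gave 4 higher and 1 lower of 12 (adjusted p = 0.18). T cell genes gave 3 higher and 2 lower of 21, 1 and 1 adjusted over the list alone (adjusted p = 0.624). B and plasma cells gave 0 higher and 4 lower of 11, 0 and 5 adjusted over the list alone (adjusted p = 0.166). NK and innate lymphoid cells gave 2 higher and 0 lower of 8, 1 and 0 adjusted over the list alone (adjusted p = 0.21). Nerve and Schwann cells gave 4 higher and 2 lower of 13 (adjusted p = 0.252). Without mouse 2 in any tissue, dendritic cells had adjusted p = 0.0487 and monocytes and neutrophils adjusted p = 0.0353. Where only 1 pair of counts is given for a list here, the counts adjusted over the list alone were equal.

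Testis was compared with each region to set the organ that makes sperm beside the duct that holds them. All 20 measured genes of meiotic spermatocytes and all 31 of spermatids and sperm were higher in testis than in caput, corpus and cauda. For spermatids and sperm the adjusted p were 9.99e-09, 3.9e-08 and 9.69e-08, and adjusted p = 0.119, 0.132 and 0.145 with an estimated correlation. For meiotic spermatocytes they were 9.59e-06, 1.21e-05 and 1.39e-05, and adjusted p = 0.0761 in each with an estimated correlation. Akap3, an anchoring protein of the sperm tail, averaged 30360 ± 758 in testis against 25.7 ± 7.09 in caput (log2 fold change 10.19, SE 0.21, adjusted p = 2.07e-13). It lies on chromosome 6 at 126853098 to 126874308 (ENSMUSG00000030344). Catsper1, a calcium channel subunit of the sperm tail, averaged 3781 ± 443 in testis against 1.33 ± 1.15 in caput (log2 fold change 10.82, SE 0.40, adjusted p = 3.49e-11). Hormad1, a protein of meiotic chromosome axes, averaged 5350 ± 191 in testis against 3.33 ± 1.53 in caput (log2 fold change 10.33, SE 0.28, adjusted p = 2.25e-12). Ddx4, a germ cell RNA helicase, averaged 20512 ± 573 in testis against 29 ± 4.36 in caput (log2 fold change 9.43, SE 0.22, adjusted p = 4.6e-13). Spermatogonial genes were not called as a list, with 10 higher and 4 lower of 15 against caput (adjusted p = 0.366) and 10 higher and 3 lower of 15 against cauda (adjusted p = 0.166). Against corpus they gave 12 higher and 3 lower of 15 (adjusted p = 0.0918), and were called with upper-quartile scaling (0.0455) or scaled to the total without mitochondrial transcripts (0.0443). Leydig cell and steroid synthesis genes gave 12 higher and 2 lower of 17 against corpus (adjusted p = 0.0303, and adjusted p = 0.159 with an estimated correlation), a call that ended with a pseudocount of 0.1 (0.0617). Against caput they gave 13 higher and 3 lower of 17 (adjusted p = 0.0626), and were called at 6 settings. These were TMM (0.0489), upper-quartile scaling (0.0448), scaling without mitochondrial transcripts (0.0443), a pseudocount of 10 (0.0305), and leaving out cauda of mouse 1 (0.05) or all of mouse 2 (0.0459), and the adjusted p reached 0.133 at others. Against cauda they gave 13 higher and 3 lower of 17 (adjusted p = 0.0306, and adjusted p = 0.159 with an estimated correlation), and up to 0.0662 at other settings. Cyp11a1, which makes pregnenolone from cholesterol, averaged 1251 ± 125 in testis against 0.333 ± 0.577 in corpus (log2 fold change 9.95, SE 0.49, adjusted p = 5.65e-10). Sertoli cell genes gave 17 higher and 2 lower of 20 against corpus (adjusted p = 0.00942, and adjusted p = 0.101 with an estimated correlation). Against cauda they gave 16 higher and 1 lower of 20 (adjusted p = 0.00862, and adjusted p = 0.101 with an estimated correlation). Against caput they were not called, with 13 higher and 7 lower of 20 (adjusted p = 0.51). Cst9, a cystatin in that list, averaged 1471 ± 116 in testis against 0.667 ± 0.577 in corpus (log2 fold change 9.85, SE 0.38, adjusted p = 5.04e-11). Proliferation genes gave 17 higher and 3 lower of 20 against caput (adjusted p = 0.0132, and adjusted p = 0.547 with an estimated correlation). Aurka, a mitotic kinase, averaged 2889 ± 213 in testis against 49 ± 8.89 in caput (log2 fold change 5.87, SE 0.20, adjusted p = 1.9e-11).

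Many epididymal secretory and epithelial genes were lower in testis. Adam7, a sperm-associated member of the ADAM family, averaged 1 ± 0 in testis against 257793 ± 15264 in caput (log2 fold change -16.97, SE 0.11, adjusted p = 6.29e-17). Its mean was 137949 ± 14436 in corpus and 104137 ± 17605 in cauda. Gpx5 averaged 0.667 ± 1.15 in testis against 549130 ± 40965 in caput (log2 fold change -18.54, SE 1.00, adjusted p = 1.42e-09). That SE also holds the spread between the corpus libraries. Crisp1 averaged 6 ± 3.61 in testis against 392879 ± 67601 in cauda (log2 fold change -15.89, SE 0.38, adjusted p = 8.56e-13). Spink5, a serine protease inhibitor, averaged 0.333 ± 0.577 in testis against 34636 ± 2651 in cauda (log2 fold change -14.74, SE 0.33, adjusted p = 4.3e-13). Lcn5 was listed at 0 in all testis libraries and averaged 35508 ± 6555 in caput. Against caput, the beta-defensins gave 2 higher and 32 lower of 36 (adjusted p = 5.77e-08, and adjusted p = 0.101 with an estimated correlation). The lipocalins gave 1 higher and 9 lower of 10 (adjusted p = 0.00018, and adjusted p = 0.0761 with an estimated correlation). Against corpus they gave 2 higher and 7 lower of 10 (adjusted p = 0.0345, and adjusted p = 0.174 with an estimated correlation), a call lost at 6 settings (up to 0.302). Against cauda they were not called, with 2 higher and 4 lower of 10 (adjusted p = 0.242). Cystatins and serine protease inhibitors gave 4 higher and 26 lower of 32 against caput (adjusted p = 3.28e-06, and adjusted p = 0.0761 with an estimated correlation). Sperm maturation proteins gave 4 higher and 30 lower of 36 against caput (adjusted p = 7.46e-07, and adjusted p = 0.201 with an estimated correlation). Among their exceptions was Spam1, a hyaluronidase of sperm, at 2024 ± 211 in testis against 2 ± 1.73 in caput (log2 fold change 9.54, SE 0.45, adjusted p = 3.66e-10). Basal cell genes gave 3 higher and 12 lower of 15 against caput (adjusted p = 0.000949, and adjusted p = 0.0761 with an estimated correlation), among them the keratin Krt5 (log2 fold change -8.52). Tight junction and epithelial barrier genes gave 7 higher and 17 lower of 24 against caput (adjusted p = 0.00085, and adjusted p = 0.0761 with an estimated correlation). The claudin Cldn8 was among the lower ones (-9.39) and N-cadherin, Cdh2, among the higher (7.38). Mitochondrially encoded transcripts gave 0 higher and 10 lower of 10 against corpus (adjusted p = 0.000513, and adjusted p = 0.423 with an estimated correlation).

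Several immune lists were lower in testis than in the epididymis. MHC class I and antigen processing genes gave 1 higher and 20 lower of 22 against cauda (adjusted p = 3.28e-06, and adjusted p = 0.0574 with an estimated correlation). B2m averaged 549 ± 48.4 in testis against 38382 ± 5483 in cauda (log2 fold change -6.12, SE 0.13, adjusted p = 2.4e-13). MHC class II genes gave 2 higher and 12 lower of 15 against caput (adjusted p = 0.00246, and adjusted p = 0.159 with an estimated correlation). Ifi30, a lysosomal thiol reductase, averaged 32 ± 8.89 in testis against 506 ± 29.7 in caput (log2 fold change -3.97, SE 0.15, adjusted p = 4.31e-11). Interferon-stimulated genes gave 4 higher and 32 lower of 41, 5 and 32 adjusted over the list alone against caput (adjusted p = 9.59e-06, and adjusted p = 0.349 with an estimated correlation). Irf9, a transcription factor of interferon signalling, averaged 88 ± 10 in testis against 1151 ± 255 in caput (log2 fold change -3.68, SE 0.14, adjusted p = 5.1e-11). Toll-like receptors and adaptors gave 4 higher and 21 lower of 28 against caput (adjusted p = 0.000768, and adjusted p = 0.159 with an estimated correlation). NF-kappa-B signalling gave 3 higher and 15 lower of 20 against caput (adjusted p = 0.0027, and adjusted p = 0.1 with an estimated correlation). Ido1, a tryptophan-degrading enzyme that restrains T cells, averaged 3.67 ± 3.06 in testis against 8354 ± 1397 in caput (log2 fold change -11.02, SE 0.57, adjusted p = 9.08e-10). Some immune genes were higher in testis. Dhx58, an RNA sensor, averaged 1099 ± 69.4 in testis against 50.7 ± 18.6 in caput (log2 fold change 4.47, SE 0.22, adjusted p = 5.92e-10). Irak3, an inhibitor of toll-like receptor signalling, averaged 1851 ± 172 in testis against 70.7 ± 10.7 in caput (log2 fold change 4.70, SE 0.16, adjusted p = 1.22e-11). Nlrc4, of the flagellin-sensing inflammasome, averaged 261 ± 27.2 in testis against 17.7 ± 2.08 in caput (log2 fold change 3.81, SE 0.24, adjusted p = 5.78e-09). Aif1, a marker of macrophages, averaged 2042 ± 62.7 in testis against 42 ± 7 in caput (log2 fold change 5.58, SE 0.14, adjusted p = 7.4e-13). The macrophage list went the other way, with 5 higher and 17 lower of 26 against caput (adjusted p = 0.023, and adjusted p = 0.568 with an estimated correlation), a call that ended with a filter of 50 (0.102). NOD-like receptors and inflammasome genes, with Nlrc4, were not called, with 7 higher and 10 lower of 20 against caput (adjusted p = 0.276). Smooth muscle gave 1 higher and 18 lower of 20 against cauda (adjusted p = 2.01e-06, and adjusted p = 0.345 with an estimated correlation). Collagens and extracellular matrix gave 0 higher and 27 lower of 29 against cauda (adjusted p = 3.9e-08, and adjusted p = 0.345 with an estimated correlation).

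Testis comparisons are relative to a shift of all genes. The median log2 fold change was 0.38 against caput, 0.41 against corpus and 0.42 against cauda under the authors' scaling. Scaling to the total without mitochondrial transcripts gave -0.17, -0.19 and -0.23. Called genes were then 10736 higher and 11822 lower than caput, 10767 and 11962 for corpus, and 10585 and 12109 for cauda. Under the authors' scaling they were 13104 and 9618, 13245 and 9690, and 13279 and 9622. Called in opposite directions under these 2 scalings were 180 genes against caput, 260 against corpus and 374 against cauda. Between cauda and caput the median went from 0.04 to 0.15 and no called gene changed direction. None of the genes given a fold change above changed direction under that scaling, upper-quartile scaling or TMM, except that mt-Nd2 has no value under the first.

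Genes were called enriched in a tissue when at least 2-fold higher than in each of the other tissues and called in all of those comparisons. They numbered 9664 in testis (5700 protein-coding), 1103 in caput (724), 635 in corpus (364) and 797 in cauda (545). Lcn9, Cst11 and Adam28 led in caput, with means of 58429 ± 4538, 22471 ± 2202 and 37638 ± 3190 there. Corpus was led by Spint4 at 19041 ± 6277, Defb22 at 11663 ± 1420 and Pate3, of a family of sperm-binding proteins, at 2628 ± 398. Leading genes in cauda included Spink14 at 1079 ± 234, Chrm2 at 847 ± 180, the amino acid transporter Slc7a15 at 7151 ± 98.6 and Serpine2 at 7295 ± 107. In testis they included Akr1cl at 1669 ± 48.3, Sept14 at 2095 ± 34.5 and the testis histone Hist1h2ba at 2985 ± 347. Raising the filter to 50 left 411 genes in corpus, 788 in caput, 546 in cauda and 6742 in testis. Without mouse 2 in any tissue, 567 genes were enriched in corpus, 1031 in caput, 716 in cauda and 9563 in testis. Pairwise counts without mouse 2 were 11200 for cauda and caput, 10282 for corpus and caput, and 8111 for cauda and corpus. Those of testis against caput, corpus and cauda were 22069, 22223 and 22209.

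**Figure D3:**
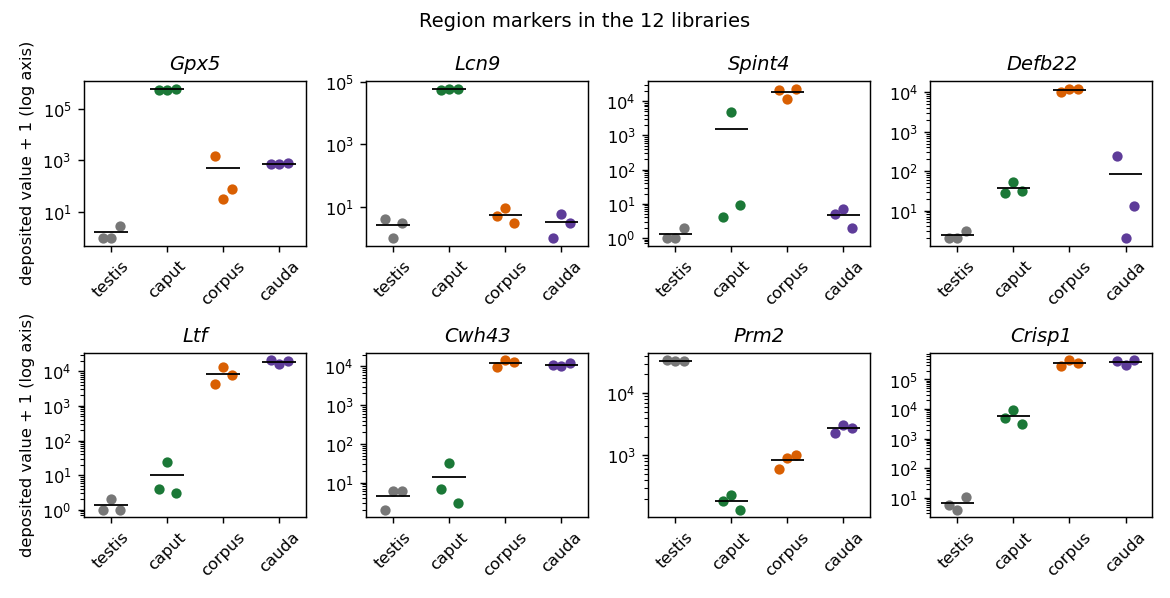
Normalised read counts plus 1 of 8 genes in the 12 libraries on log axes, with points for single libraries and lines for the mean of each tissue. Prm2 was highest in testis, Gpx5 and Lcn9 in caput, Spint4 and Defb22 in corpus, and Ltf in cauda.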

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

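All alternatives but the scaling to the total without mitochondrial transcripts were set before the values were seen, and that scaling was chosen afterwards. Of the 10 counts of genes, all but 2 values stayed within 1.5 times the main count. A filter of 50 gave 411 genes enriched in corpus against 635, where fewer genes were tested. Leaving out mouse 3 gave 6515 genes between cauda and corpus against 9864, where fewer libraries entered. Over all libraries and mice left out that count was 6515 to 9899; the ranges were 9846 to 13270 for cauda and caput, 8205 to 11820 for corpus and caput, and 21352 to 22829, 21583 to 22969 and 21571 to 23014 for testis against caput, corpus and cauda. Every gene given a fold change kept its direction under each alternative that gave it a value. Genes left out by an alternative had none there, such as mt-Nd2 without mitochondrial transcripts and Prm2 with testis-high genes removed. Those that missed the threshold under some alternative were Spint4 and Spint5 between corpus and caput, when mouse 1 or mouse 3 was left out, Hoxd9 between cauda and caput, when mouse 3 was left out (adjusted p = 0.0938), and Hoxc5, when mouse 2, mouse 3, caput of mouse 2 or cauda of mouse 1 was left out. With the mouse as a block, which pairs the libraries, the counts were 12613, 11293 and 9479 within the epididymis and 22621, 22802 and 22789 for testis against caput, corpus and cauda, and 9663, 1101, 631 and 795 genes were enriched in testis, caput, corpus and cauda. Of the genes called without the block, 12464 of 13044 were called with it between cauda and caput, 11131 of 11713 between corpus and caput, and 9283 of 9864 between cauda and corpus. Of the list calls, the block changed the 3 given with it in the report. No list call changed direction. Using camera with an estimated correlation ended 103 list calls. Some were of lists with an estimate below the preset of 0.01, so a correlation above the preset cannot have ended these. Between cauda and caput, lipocalins (estimate -0.037) went from adjusted p = 1.7e-05 to 0.0574, and Sertoli cells (-0.021) from 0.00133 to 0.0761. Other lists had an estimate above it, such as smooth muscle (0.474, from 1.49e-08 to 0.255). What ended the calls was not tested. The edgeR test planned on recovered reads was not run.

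In each comparison of 2 tissues, 10 splits of the 6 libraries into groups of 3 are too few for a share under 0.05. The real split was 1 of 10 with a count as large in each of the 6 comparisons, and the highest other count was 2 for cauda and caput, 1 for corpus and caput, 2 for cauda and corpus, and 0 for testis against caput, corpus and cauda; 4 of the splits part all 3 mice. For genes enriched in testis, 1 of 100 splits of the 12 libraries gave a count as large, the real one (9664 against at most 46). That share is under 0.05, with labels exchanged without regard to the mouse. Testis and epididymal libraries correlated at only 0.497 to 0.548, so splits that mix them could hardly match the real count. For the epididymal regions the testis libraries stayed in place and 100 splits of the other 9 libraries were drawn, a test chosen after the values were seen. A count as large came from 1 for caput (1103 against at most 1097), 2 for cauda (797 against at most 1094) and 5 for corpus (635 against at most 1078). Of the splits drawn, 4 for caput, 4 for corpus and 3 for cauda kept the 3 libraries of 1 region together under the name tested. Counts as large came only from the real split and from such splits. These shares therefore rank real regions and cannot decide on chance. Without such splits the highest count was 0 in each. In 20 simulated sets with no gene changed, the highest enriched count in any region was 0. Depth limits what can be said of genes near a value of 10.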

Other observations

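The Hox genes and the tests below were chosen after the values were seen, except the test of nuclear respiratory chain genes. Of 21 Hox genes of paralogue groups 1 to 8, which pattern the front of the body axis in embryos, limma called 1 higher and 11 lower in cauda than in caput, and of 8 genes of groups 9 to 13, which pattern its rear, 6 higher and 1 lower. Hoxc10 had a log2 fold change of 4.83 (SE 0.22, adjusted p = 4.63e-09) and Hoxd10 of 3.64 (SE 0.48, adjusted p = 3.92e-05). Hoxc8 had one of -2.32 (SE 0.21, adjusted p = 1.53e-06) and Hoxa3 of -2.01 (SE 0.27, adjusted p = 5.16e-05), while Hoxb1 was listed at 0 in cauda against a mean of 42 in caput. The exceptions were Hoxc5, higher by 0.81 (adjusted p = 0.0192), and Hoxd9, at -0.45 (adjusted p = 0.00338). Hoxc5 lost the call without caput of mouse 2 (adjusted p = 0.0738) or cauda of mouse 1 (0.07), with 0.0036 to 0.139 over its alternatives. The groups of Hox genes were counted only and not tested as sets.

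Caput of mouse 2 held transcripts typical of corpus, such as Spint4 at 4675 against 3 and 8 in the caput libraries of mice 1 and 3. RNA of the whole corpus mixed into that library would raise all corpus genes by 1 share of their corpus level, but of 116 genes high in corpus, 34.5% had an excess under 1% of it and 33 had one above 5%, up to 20.63% for Spint4, which argues against it. Region borders lying further along the duct in that mouse stay open: over the 116 genes, the excess in caput and the deficit in corpus of mouse 2 had a Spearman rho of 0.25, short of the limit of 0.3 set for it, against 0.26 over 117 genes and 0.27 over 104 genes chosen in the same way for mice 1 and 3, across genes that are not independent replicates. The median log2 excess in caput was 0.92 in mouse 2 against -0.3 and -0.32 in mice 1 and 3. The median log2 deficit in corpus was -0.26 in mouse 2 against 0.34 and 0.02, so these genes were not lower in its corpus as a group. A shifted border would move only a part of the corpus, so a median over all 116 genes cannot decide on it. The genes with the largest excess, from Spint4 at 20.63% to Faim2 at 11.08%, were all lower in corpus of mouse 2. Spint4 and Defb23 were at 11858 and 8835 there against means of 22632.5 and 16671 in mice 1 and 3. Others with a smaller excess were higher, such as Crisp1 at 442501 against 320605. No group of the design offers a biological explanation for a single mouse, and none was tested.

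Transcripts of spermatids and sperm were found in the epididymal libraries, with caput below corpus below cauda for 27 of 31 genes and a cauda level of 0.28 to 16.4% of that in testis. Testis RNA carried into the cauda libraries would give these genes 1 ratio to testis, but 51.6% of them were outside 2-fold of the median ratio on the same side in all 3 cauda libraries, 9 below and 7 above, which argues against it as the whole cause. As a part of the cause, the test set for it left it open. The spermatid median of 2.17% was 3.84 times the 10th percentile of 752 abundant testis-enriched genes, 0.565%. That lay between the limits set for either answer, and the 90th percentile of those genes was 28.1%. At 1 ratio for all genes, such a part could be no larger than the lowest cauda level of any testis gene. Among spermatid genes the lowest was 0.28%, for Akap3. Of genes with a mean of at least 100 in testis, it was 0.193% for meiotic spermatocytes and 0% for the Sertoli and Leydig lists. Gm14569, at 7627.7 in testis, was at least 11.51 log2 units higher there than in every other tissue. These levels argue against testis RNA as more than a small part of the spermatid median. RNA of sperm stored in the duct would favour late germ cells; the spermatid median was 2.56 times that of meiotic spermatocytes, 0.85%, short of the 3-fold set for it. The tissues themselves differ by design, and expression by epididymal cells stays open and untested.

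The share of mitochondrial transcripts was higher in corpus than in caput. Unequal removal of ribosomal RNA would leave the mitochondrial messenger RNAs behind mt-Rnr2, but their median log2 change was 1.52 (8 genes, 0.89 to 2.06), which argues against it as the whole cause. More mitochondria per cell may be a candidate explanation and stays open: nuclear genes of the respiratory chain, the test set before the result was seen, had a median log2 change of 0.22 over 71 genes, 25 higher and 5 lower, between the limits of 0.2 and 0.5.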
